A study of Danio rerio with 8 samples.

How the data were processed

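Ribosome-protected RNA fragments were profiled in zebrafish (Danio rerio) embryos at 4 hours post fertilization (hpf). Per the labels' protocols, embryos were treated with cycloheximide, which halts elongating ribosomes, and lysed. The lysate was digested with RNase I and passed over a spin column, ribosomal RNA was depleted, fragments of a footprint's length were taken from a gel, and libraries were made with a small RNA kit. The labels also give the molecule as polyA RNA, at odds with this protocol, and the protocol was followed. The 8 samples formed 4 groups of 2, namely wild type embryos (WT), ddx3xb mutant embryos (KO), mutant embryos injected with a construct labelled ddx3xbFL (KO_FL) and mutant embryos injected with a construct labelled ddx3xb deltaN (KO_dN). Groups were taken from the genotype label for the uninjected embryos and from the sample titles for the injected ones.

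The deposited values were FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library), 1 value per gene and group. Per the series design text, the authors made each deposited file from both replicates, and it was read as their mean. The submitters' processing notes name cutadapt 1.13, Trimmomatic 0.36, Bowtie, TopHat2 2.1.1 and Cufflinks 2.2.1, and the genome build Zv9. Their settings, and any removal of ribosomal RNA reads after sequencing, are not given in the sources used here. The 4 files held 33737 gene identifiers. The WT file differed from the other 3 in layout: it had another separator, was not sorted, lacked 3 identifiers, and listed 101 identifiers on more than 1 line, 218 lines in all. Those 101 and the 3 absent from the WT file were left out of every group, which left 33633 identifiers, and summing them was tried as an alternative. The series design text names the mutant and injected groups and not WT. Symbols came from a table of gene names and matched 21863 identifiers. They are written as that table gives them, so that many zebrafish genes carry capital letters.

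FPKM divides by the reads mapped in each library, so its low values still hold the worth of a single read. Among genes below 0.1 FPKM in 2 groups, 4 values were chosen from the commonest log2 ratios. The rule was that their outer and inner pairs have the same sum within 0.02, as a mean of 2 libraries with a single read in either gives. The equal sums were thus required and are not a finding. The 4 values held 16.3 to 16.8% of those genes in the pairs of KO, KO_FL and KO_dN. From these steps the 6 libraries of KO, KO_FL and KO_dN could be ranked in depth, and 141 genes with a single read in each of those groups then gave the steps of WT, from clusters of 13 and 14 of them, so the depth of WT rests on few genes, and on a scale shared with the other files. The numbers of reads themselves stayed unknown. With 1 value per group there was no error, no replicate check and no p-value for any gene or list, and differences are described as values. Whether the replicates came from separate clutches is not stated.

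Log2 ratios were computed as log2((a + 1)/(b + 1)), with a pseudocount of 1 FPKM, over the 7698 genes whose mean over the 4 groups was at least 1 FPKM. A fold on this scale understates the change of low genes. Genes at least 2-fold higher or lower were counted in 6 comparisons with the values as deposited. Because the median gene differed between groups, counts are also given for ratios centred on their median and for values scaled by median of ratios over 3177 genes at 1 FPKM or more in all groups. The scaling factors were 3.40 for WT, 0.73 for KO, 0.90 for KO_FL and 0.45 for KO_dN. A relative log2 ratio is the ratio minus the median of all 7698 genes. The scaled values were chosen after seeing the data.

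The 29 gene lists were fixed before the data were examined: ddx3 genes, maternal pluripotency factors, early zygotic transcription factors, zygotic signalling genes, maternal oocyte genes, germ plasm genes, mRNA decay and deadenylation, translation initiation factors, translation elongation and termination, cytosolic ribosomal proteins, mitochondrial ribosomal proteins, mitochondrially encoded genes, nuclear OXPHOS genes (respiratory chain and ATP synthase), proteasome subunits, histones, cell cycle genes, Wnt pathway genes, integrated stress response genes, heat shock and chaperone genes, enveloping layer markers, yolk syncytial layer markers, vitellogenins, later tissue markers, cytoskeleton genes, nuclear pore and import genes, splicing factor genes, DEAD-box helicases, chromatin and DNA methylation genes, and 1 further list that is counted among the lists but not reported here. The pattern that finds ribosomal protein symbols also took 11 identifiers of S6 kinases and a binding protein, which were removed. For each list of 3 or more measured genes, the offset is the list's median log2 ratio minus that of all genes. It is placed among 10000 random lists of the same size matched on mean expression in 10 bins, as a description of these libraries. A list is said to lie outside the random lists when its offset fell outside their middle 95%. Members were counted as higher or lower when their relative ratio reached 1.5-fold. A group of small RNA genes was added after seeing the data.

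The genes named in the text followed a rule fixed before the data were examined: both ddx3 genes; the 12 highest and 12 lowest KO/WT ratios, and the 6 highest and 6 lowest KO_FL/KO, KO_dN/KO and KO_FL/KO_dN ratios, among the 848 genes with an informative symbol and a mean of at least 10 FPKM; and for each list the 2 members with the highest mean and the 2 with the largest absolute KO/WT ratio. Other members of a list that are named were chosen after their values were seen. Genes different in KO were read in KO_FL/KO_dN, which shares no library with that choice. Ratios were correlated across genes only in pairs that share no group, and log2 levels between groups.

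The steps were tested on simulated data with known answers. In simulated scaled values for KO/WT over 7698 genes, 94.0% of 50 genes set 4-fold higher and 48.0% of 50 set 4-fold lower passed 2-fold, since the pseudocount draws low genes together. Of 7458 unchanged genes, 0 passed. The simulated noise was set far below the SD of the real scaled KO/WT log2 ratios (1.20), so this gives no rate of false positives. A list of 40 genes set to a log2 change of -1 came out at an offset of -0.54. The depth steps of all groups came out within 0.005 on the log2 scale over 33633 simulated genes. Alternatives were a pseudocount of 0.1 or 5, no filter or a minimum of 5 FPKM, centring, rescaling to TPM, quantile normalization, rescaling without the 50 highest genes, thresholds of 1.5-fold and 4-fold, and informative symbols only; scaling by median of ratios, summed identifiers and a filter that leaves out WT were added after seeing the data. A planned comparison of the ratios with UTR length, coding length and GC content was not run, as no genome was used here. Without RNA-seq of the same embryos, the values are footprint densities, in which transcript abundance and translation are not separated. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.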

Results

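Ribosome footprints were measured in zebrafish embryos at 4 hpf, a blastula stage at which the embryo's own genome is being switched on and maternal transcripts are being cleared. The 8 samples comprised wild type embryos (WT), embryos mutant for ddx3xb (KO), and mutant embryos injected with a construct labelled ddx3xbFL (KO_FL) or ddx3xb deltaN (KO_dN), 2 samples each. ddx3xb encodes a DEAD-box RNA helicase of the DDX3 family, which is known to act in translation initiation. Each group had 1 deposited FPKM value per gene, the authors' mean of both replicates, so no value below has a replicate error.

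The FPKM summed to 2050730 over all listed genes in WT, 364175 in KO, 395843 in KO_FL and 190755 in KO_dN. Of 33633 identifiers, 10889 reached 1 FPKM in WT, 4912 in KO, 5515 in KO_FL and 3458 in KO_dN. From the worth of a single read, and if the 4 files share a scale, the libraries had depths of 100% and 66.9% (KO_FL), 91.4% and 57.0% (KO), 75.8% and 71.7% (KO_dN), and 34.6% and 27.2% (WT) of the deepest. On that condition the WT libraries were the shallowest, with the highest FPKM values. Mapped reads outside the listed genes also enter the divisor of FPKM and lower every value of a group, and their number is not given in the sources used here, so the shift between WT and the other groups as deposited is not a measure of footprints per embryo. Across 7698 genes, log2 levels correlated with a Pearson r of 0.92 to 0.93 between any pair of KO, KO_FL and KO_dN, and of 0.72 to 0.79 between each of them and WT; genes are not independent replicates.

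The targeted gene was read in all groups. ddx3xb (ENSDARG00000005774) stood at 129 FPKM in WT and 14.7 in KO, a log2 ratio of -3.05, close to the median of -2.83 over the 769 genes of the highest expression bin, so its level does not check the KO label. It stood at 76.7 FPKM in KO_FL and 126.5 in KO_dN, so both injected groups held more ddx3xb footprints than KO, with log2 ratios of 2.31 and 3.02 where that bin had medians of 0.56 and -0.70. Its paralogue ddx3xa (ENSDARG00000020573) stood at 28.1, 11.1, 11.4 and 3.18 FPKM in WT, KO, KO_FL and KO_dN. Its KO/WT ratio of -1.26 turned to 0.68 relative to all genes, 1.101 with TPM, 1.15 with quantile normalization and 0.81 with scaled values. The position of the mutation, and how much of the gene either construct carries, are not given in the sources used here.

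The comparison of KO with WT asked how footprints differed in ddx3xb mutant embryos. Genes of the cytosolic ribosome stood low in KO: the median of 72 ribosomal protein genes was 25.1 FPKM in WT and 1.62 in KO, and relative to all genes 62 of them were at least 1.5-fold lower and 1 was higher. RPLP1, of the ribosomal stalk, went from 316 FPKM in WT to 2.68 in KO (log2 ratio -6.43), RPL35 from 114 to 1.43 (-5.56), RPS25 from 182 to 3.46 (-5.36), rplp2l from 119 to 2.34 (-5.16) and RPS24 from 70 to 1.04 (-5.12). HSPB1, a small heat shock protein, had the lowest ratio of any named gene, with 2427 FPKM in WT and 18.6 in KO (-6.95). ZAR1, a maternal oocyte factor, went the other way, from 4.18 to 32.5 FPKM (2.69).

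As deposited, 191 genes were at least 2-fold higher and 6399 at least 2-fold lower in KO, because the median gene had a log2 ratio of -1.94. Centred on that median, 1201 were higher and 1296 lower, and with scaled values 721 and 1565. The filter used the deposited mean, in which WT weighs most, so it favoured genes high in WT, also in the scaled counts. Without WT in the mean, 4850 genes passed, and scaling was not combined with that filter. Other low genes in KO were SPATA6 at 204 FPKM in WT and 1.36 in KO (-6.44), stm, which encodes the otolith protein starmaker, at 148 and 0.84 (-6.34), the mitochondrial MT-CYB at 2002 and 43.0 (-5.51), DNAJB13 at 47.0 and 0.30 (-5.20) and PNRC2, a decapping cofactor, at 2236 and 63.2 (-5.12). SAT1, a spermidine acetyltransferase, had 42.8 FPKM in WT and was listed at 0 in KO. High genes were NKX2-1 at 0.15 FPKM in WT and 49.8 in KO (5.46), fmn2a at 9.04 and 144 (3.85), YWHAG at 54.2 and 721 (3.71), the RNA-binding protein gene QKI at 5.55 and 80.2 (3.63), SLC38A3 at 0.62 and 11.7 (2.97), the kinase gene RPS6KA2 at 6.99 and 55.8 (2.83), C1H4orf33 at 6.68 and 38.2 (2.35), CSRNP2 at 137 and 651 (2.24), MARK2 at 5.75 and 26.2 (2.01), FAM171B at 5.11 and 21.7 (1.89) and SLC5A10 at 4.62 and 19.7 (1.88). Of the 848 genes in this pool, 31 were higher in KO as deposited and 16 of them by 2-fold.

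**Figure D1:**
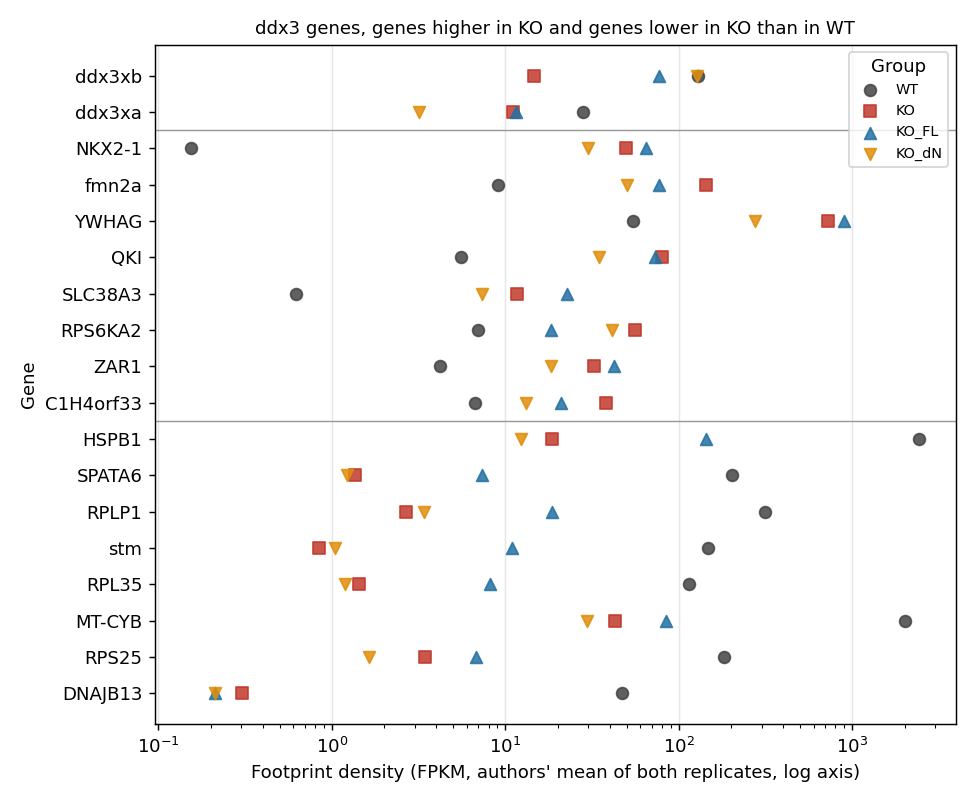
Footprint density (FPKM, log axis) of the ddx3 genes, the 8 named genes highest in KO over WT and the 8 lowest that were above 0 in all groups, with 1 marker per group for the authors' mean of both replicates. HSPB1 stands at 2427 FPKM in WT, 18.6 in KO, 144 in KO_FL and 12.3 in KO_dN.

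Among the 26 lists with an offset, 1 lay outside the random lists in KO/WT, where chance would place 1.3. This was the ribosomal protein list, with an offset of -1.53 and 0 of 10000 random lists as low; its offset with scaled values was -1.23. The 13 mitochondrially encoded genes had an offset of -1.39, with 12 lower, but lay at percentile 15.9 of the random lists. The highest expression bin ran from a mean of 22.9 to 81421.5 FPKM, so the match was loose for the strongest genes. MT-ND6 had 2043 FPKM in WT and 92.9 in KO, and MT-CO2 868 and 32.9. Mitochondrial ribosomal proteins had an offset of -0.10 (percentile 4.07; 8 of 29 higher and 10 lower) but lay below the random lists with a pseudocount of 0.1 (-0.49), TPM (-0.37) and quantile normalization (-0.33), with MRPS25 at 36.4 and 2.61 FPKM and mrpl39 at 17.6 and 0.35. Nuclear OXPHOS genes had an offset of -0.01 (percentile 44.7; 13 of 47 higher and 13 lower), with ATP5F1A at 199 and 6.59 FPKM.

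Zygotic and maternal lists lay within the random range as deposited. The filter left 10 of 28 early zygotic transcription factors and 13 of 23 zygotic signalling genes, and so favoured members high in WT. Early zygotic transcription factors had an offset of -0.66 (percentile 4.58), with 6 of 10 lower and 0 higher: tbx16, of the mesoderm, stood at 33.5 FPKM in WT and 1.02 in KO, noto, of the notochord, at 19.7 and 1.67, and irx7 at 36.0 and 3.78. Zygotic signalling genes had an offset of -0.06 (percentile 24.7; 2 of 13 higher and 4 lower), with FGF8 at 11.4 and 0.20 FPKM and the BMP antagonist gene chrd at 18.5 and 0.99. Maternal pluripotency factors had an offset of 0.75 (percentile 91.7; 2 of 3 higher), with nanog at 118 and 69.7 FPKM, pou5f3 at 108 and 29.1 and sox19b at 22.8 and 9.46. Maternal oocyte genes had an offset of 0.27 (percentile 93.8; 9 of 23 higher and 4 lower), and 0.43 with scaled values, which was outside the random lists; CCNB1 stood at 197 and 46.6 FPKM, gdf3 at 75 and 29.8, plk1 at 71.3 and 3.26 and aurka at 25.2 and 0.89. Germ plasm genes had an offset of 0.14 (percentile 65.7; 3 of 15 higher and 2 lower), with DDX4 at 35.4 and 6.40 FPKM and CELF1 at 22.7 and 9.56.

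Outer and yolk cell types were also measured. The filter left 11 of 23 enveloping layer markers and 5 of 20 yolk syncytial layer markers. Enveloping layer markers had an offset of -0.44 (percentile 19.3; 1 of 11 higher and 5 lower), with grhl3 at 149 FPKM in WT and 8.36 in KO, krt8 at 19.1 and 0.59 and epcam at 73.9 and 18.6. Yolk syncytial layer markers had an offset of -0.72 (percentile 15.0; 4 of 5 lower), and of -1.12 with a pseudocount of 5, below the random lists, with mxtx1 at 17.7 and 0.15 FPKM, apoeb at 31.1 and 3.37 and ctsla at 375 and 79.6. Of 7 vitellogenins and 23 later tissue markers, 0 passed the filter; their highest values in any group were 0.34 and 1.56 FPKM.

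The lists of the translation machinery outside the ribosome stayed near the median gene. Translation initiation factors had an offset of -0.24 (percentile 33.2; 9 of 42 higher and 14 lower), with pabpc1a at 1873 and 79.4 FPKM, eif4a1a at 369 and 52.7 and EIF2S2 at 60.7 and 2.69. Translation elongation and termination had an offset of 0.08 (percentile 61.1, 0 of 8 higher and 2 lower), with eef1a1l1 at 147 and 34.5 FPKM and ETF1 at 227 and 20.5. Under the 6 alternatives the offset of this list was -0.39 to -0.03, still among the random lists. mRNA decay and deadenylation had an offset of 0.04 (percentile 74.1; 8 of 34 higher and 6 lower), with YBX1 at 204 and 177 FPKM and PUM3 at 52.2 and 2.98. DEAD-box helicases had an offset of -0.25 (percentile 28.6; 7 of 28 higher and 10 lower), with DDX21 at 46.8 and 4.59 FPKM.

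The remaining lists reported here also lay within the random range as deposited. Offsets were -0.21 for proteasome subunits (PSMD1 at 47.0 FPKM in WT and 4.80 in KO), -0.06 for histones (hist1h2a4 at 663 and 51.8), -0.23 for cell cycle genes (GMNN at 526 and 96.6), -0.16 for Wnt pathway genes (CTNNB1 at 27.2 and 11), 0.09 for integrated stress response genes (XBP1 at 43.6 and 1.65) and -0.24 for heat shock and chaperone genes (HSP90AB1 at 791 and 56.4). They were 0.29 for cytoskeleton genes (CFL1 at 789 and 44.8), 0.23 for nuclear pore and import genes (RAN at 140 and 9.99), -0.27 for splicing factor genes (SNRPD3 at 215 and 33.6) and -0.54 for chromatin and DNA methylation genes (hmga1a at 1972 and 122). With scaled values the nuclear pore and import list, at 0.33, lay above the random lists.

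**Figure D2:**
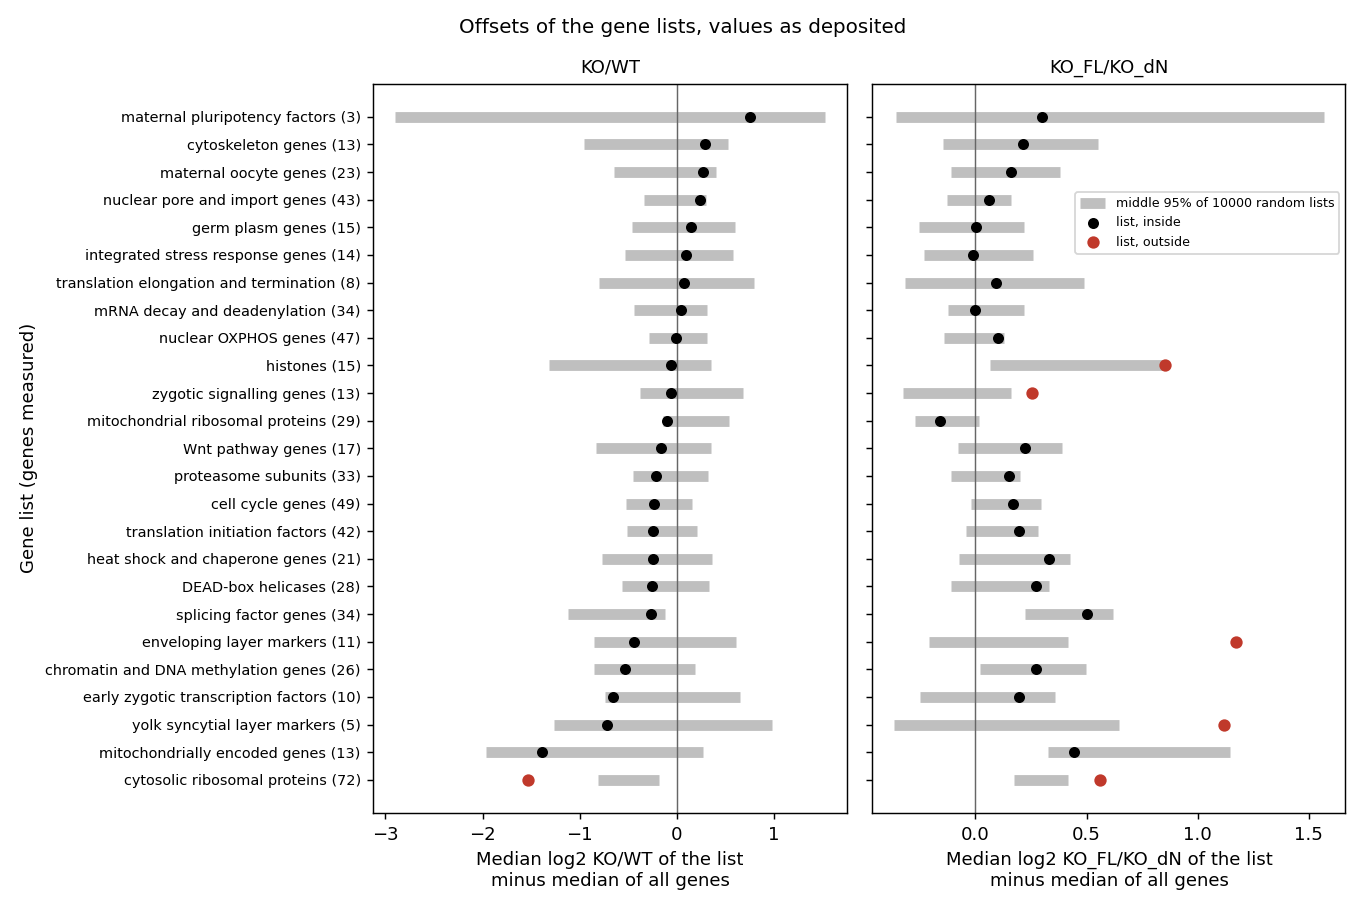
Median log2 ratio of each reported gene list minus that of all 7698 genes, as deposited, for KO/WT (left) and KO_FL/KO_dN (right); grey bars span the middle 95% of 10000 random lists of the same size and expression level. Ribosomal protein genes lie below their bar at -1.53 in KO/WT and above it at 0.56 in KO_FL/KO_dN.

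The comparison of KO_FL with KO asked what differed in mutant embryos after injection of ddx3xbFL. The samples hold no mutant embryos injected with a control, so injection itself cannot be told apart from a construct here or in KO_dN/KO. Titles of the injected samples are also worded differently from those of KO, and whether the groups were handled together is not stated. Ribosomal protein genes stood higher in KO_FL, with a median of 4.20 against 1.62 FPKM and 52 of 72 at least 1.5-fold higher relative to all genes and 0 lower. Enveloping layer markers had 7 of 11 higher and 1 lower, and a median of 4.50 against 0.79 FPKM; krt8 stood at 6.49 against 0.59 and krt18a.1 at 19.0 against 4.30. The genes with the highest ratios were capza1a, an actin capping subunit, at 32.7 against 0.95 FPKM (log2 ratio 4.11), HSPB1 at 144 against 18.6 (2.89), stm at 10.9 against 0.84 (2.69), crp2 at 16.3 against 1.88 (2.59), RPLP1 at 18.6 against 2.68 (2.41) and ddx3xb (2.31). The lowest were SPTAN1, a spectrin, at 6.55 against 23.9 FPKM (-1.72), RPS6KA2 at 18.3 against 55.8 (-1.55), CSRNP2 at 280 against 651 (-1.22), DENND5B at 17.6 against 41.9 (-1.21), cryba1l2 at 10.3 against 24.3 (-1.16) and IKZF5 at 1.34 against 4.20 (-1.15).

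In all, 469 genes were at least 2-fold higher and 147 lower in KO_FL than in KO (363 and 203 centred, 359 and 243 scaled), with a median log2 ratio of 0.18. Rescaled without the 50 highest genes, 333 were higher and 370 lower, so the side with more genes depended on the scale. Of the 26 lists, 6 lay above the random lists: enveloping layer markers (offset 1.01), yolk syncytial layer markers (0.95; 3 of 5 higher), ribosomal proteins (0.76), zygotic signalling genes (0.50; 5 of 13 higher and 0 lower), early zygotic transcription factors (0.49; 5 of 10 higher and 0 lower) and nuclear OXPHOS genes (0.14; 11 of 47 higher and 2 lower). With a pseudocount of 5, early zygotic transcription factors fell back among the random lists, at 0.116. Among zygotic genes, tbx16 stood at 5.73 FPKM in KO_FL against 1.02 in KO, chrd at 4.88 against 0.99 and WNT8A at 3.87 against 0.35. With scaled values maternal oocyte genes lay below the random lists at -0.19, and proteasome subunits above them at 0.15. KO_FL/KO shares the KO libraries with KO/WT, so genes picked as low in KO come out higher in KO_FL by chance alone, and the pair of comparisons was not correlated.

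The comparison of KO_dN with KO asked the same for the deltaN construct. The ribosomal protein genes had a lower median as deposited, 1.35 against 1.62 FPKM, but relative to all genes 11 of 72 were higher and 1 lower, and enveloping layer markers had 0 of 11 higher and 1 lower. The highest ratios were ddx3xb (3.02), SAT1 at 2.27 FPKM against a gene listed at 0, the sterol-binding protein gene OSBP at 5.50 against 1.55 (1.35), RPL13A at 2.72 against 1.68 (0.47), MKNK2 at 2.65 against 1.66 (0.46) and BCKDHB at 12.7 against 9.44 (0.39). The lowest were ZMYM2, a zinc finger protein gene, at 1.04 against 17.8 FPKM (-3.20), the cap-binding protein gene eif4e1c at 1.84 against 20.5 (-2.92), EZR, an actin linker, at 2.90 against 16.8 (-2.19), RFC1 at 1.36 against 7.84 (-1.91), the arginine methyltransferase gene PRMT1 at 5.22 against 18.8 (-1.67) and MSI2 at 8.99 against 30.1 (-1.64).

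As deposited, 91 genes were at least 2-fold higher and 462 lower in KO_dN than in KO, with a median log2 ratio of -0.36. Centred counts were 131 and 151, and scaled counts 193 and 144, so that the side with more genes depended on the scale. Of the 26 lists, 4 lay above the random lists: zygotic signalling genes (offset 0.28), early zygotic transcription factors (0.22), ribosomal proteins (0.18) and nuclear OXPHOS genes (0.12). The zygotic lists fell back among the random lists with scaled values, at 0.06 and 0.10, and each under 4 of the other 5 alternatives, while with scaled values ribosomal proteins (0.27) and nuclear OXPHOS genes (0.14) did not, and mitochondrially encoded genes (0.36) lay above them. Nuclear OXPHOS genes fell back at a pseudocount of 5, with an offset of 0.038.

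The comparison of KO_FL with KO_dN set the constructs side by side without the KO libraries. Relative to all genes, the ribosomal protein and outer-layer lists stood higher with ddx3xbFL. The ribosomal protein genes had a median of 4.20 FPKM in KO_FL and 1.35 in KO_dN, with 35 of 72 higher and 1 lower relative to all genes. Among enveloping layer markers 7 of 11 were higher and 1 lower, with krt18a.1 at 19.0 FPKM against 2.04, epcam at 31.6 against 7.91 and krt92, chosen after its values were seen, the other way at 1.47 against 2.09. Of the yolk syncytial layer markers 4 of 5 were higher, with ctsla at 128 against 40 and apoeb at 14.6 against 2.65. The highest ratios were capza1a at 32.7 against 0.45 FPKM (4.54), HSPB1 at 144 against 12.3 (3.44), crp2 (3.18), ZMYM2 at 16.0 against 1.04 (3.06), MXI1, a MAX-binding repressor, at 38.2 against 4.20 (2.92) and krt18a.1 (2.72). The lowest were SPTAN1 at 6.55 against 16.5 FPKM (-1.21), RPS6KA2 at 18.3 against 41.2 (-1.12), DENND5B (-0.84), ddx3xb itself (-0.71), IKZF5 (-0.68) and the cyclin gene CCNB2 at 31.5 against 46.4 (-0.54).

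As deposited, 1481 genes were at least 2-fold higher and 72 lower in KO_FL, with a median log2 ratio of 0.54, against 464 and 182 centred and 353 and 290 scaled. Of the 26 lists, 5 lay above the random lists: enveloping layer markers (offset 1.17), yolk syncytial layer markers (1.12), histones (0.85; 10 of 15 higher), ribosomal proteins (0.56) and zygotic signalling genes (0.25; 5 of 13 higher and 0 lower). Histones fell back among the random lists under all 6 alternatives (0.36 scaled), and yolk syncytial layer markers with a pseudocount of 5 (0.42) and at a mean of at least 5 FPKM (0.86). With scaled values, early zygotic transcription factors (0.52, and 0.19 as deposited), nuclear OXPHOS genes (0.16, and 0.10) and DEAD-box helicases (0.25, and 0.27) lay above the random lists, which they did not as deposited. Scaled offsets were 1.14 for enveloping layer, 0.74 for yolk syncytial layer, 0.50 for ribosomal protein and 0.55 for zygotic signalling genes.

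**Figure D3:**
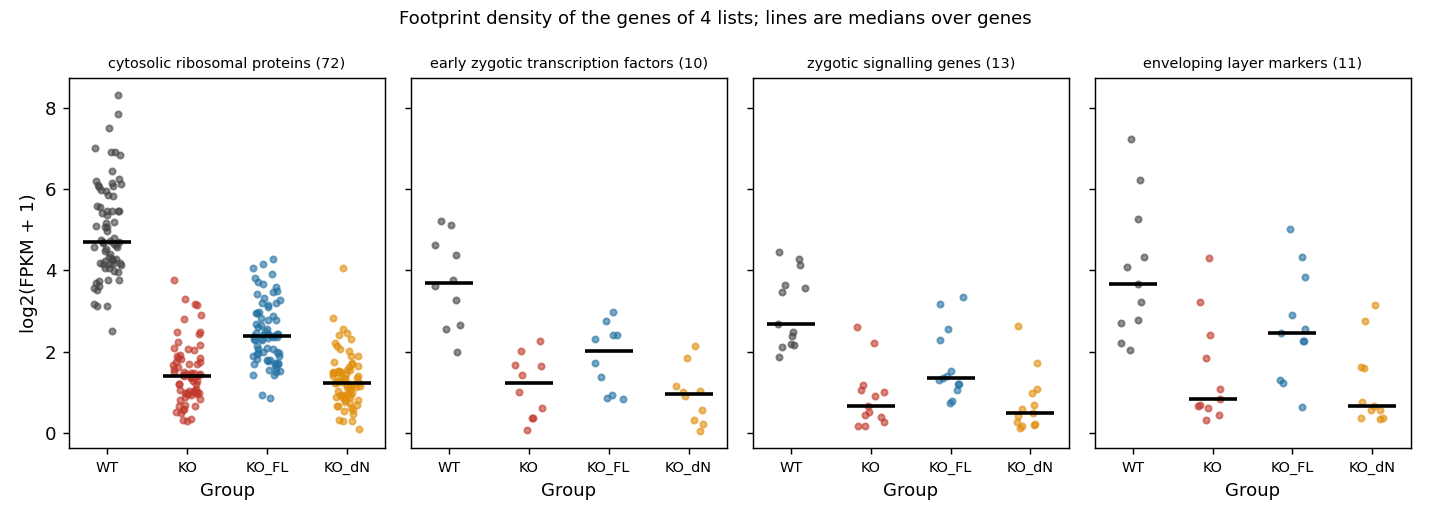
log2(FPKM + 1) of each gene of 4 lists in the 4 groups, 1 point per gene, with black lines at the median over genes. The ribosomal protein genes have a median of 25.1 FPKM in WT, 1.62 in KO, 4.20 in KO_FL and 1.35 in KO_dN.

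Genes that differed between KO and WT were then read in KO_FL/KO_dN. Of the 1565 genes at least 2-fold lower in KO with scaled values, 65.4% (exact binomial interval 63.0 to 67.8, over genes as counted items) had a KO_FL/KO_dN ratio above that of the median gene. Random genes matched on the deposited mean over the 4 groups gave 53.2 to 57.4%. WT weighs most in that mean, so the random genes were not matched on their level in KO_FL and KO_dN. Of the 721 higher in KO, 30.9% (27.6 to 34.4) did, where random genes gave 50.2 to 57.0%. As deposited, the shares were 51.6% of 6399 lower genes (50.4 to 52.8; random genes 50.8 to 51.6) and 26.7% of 191 higher genes (20.6 to 33.6; random genes 50.8 to 62.8). With ratios centred, they were 70.9% of 1296 and 42% of 1201, and the random ranges were 72.0 to 75.8% and 42.5 to 46.8%. The share of lower genes thus lay below that of random genes when centred and above it when scaled.

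Across all 7698 genes, WT/KO and KO_FL/KO_dN, which share no group, correlated with a Spearman rho of 0.24 and a Pearson r of 0.25, and with scaled values of 0.29 and 0.28. Within 10 bins of expression level the mean rho was -0.02 as deposited and 0.27 (0.21 to 0.35) scaled. Of the other disjoint pairs, WT/KO_FL with KO/KO_dN had a rho of -0.04 and an r of -0.02, and WT/KO_dN with KO/KO_FL a rho of -0.30 and an r of -0.28; their mean rho within bins was -0.25 and -0.18 as deposited, and 0.013 and -0.28 scaled. Genes are not independent replicates, and these correlations carry no p-value.

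Set against WT, both injected groups remained far from it. HSPB1 stood at 2427 FPKM in WT, 144 in KO_FL and 12.3 in KO_dN, RPLP1 at 316, 18.6 and 3.39, and DNAJB13 at 47.0, 0.21 and 0.21. These genes were named for their low KO/WT ratios, which share the WT libraries, so their distance from WT follows in part from that choice. A scale factor or separate processing of the WT file cannot be told apart from a distance of the embryos. capza1a and MXI1 were above WT in KO_FL, with 32.7 against 8.91 FPKM and 38.2 against 6.49. As deposited, 167 genes were at least 2-fold higher and 6106 lower in KO_FL than in WT, with a median log2 ratio of -1.74 (1114 and 1069 centred, 614 and 1255 scaled). In KO_dN, 133 were higher and 6942 lower, with a median of -2.26 (1099 and 1472 centred, 735 and 1660 scaled). With TPM more genes were higher than lower in both, 1269 and 982 in KO_FL and 1433 and 1327 in KO_dN, so the side depended on the scale. The TPM divisor includes RNAs that are not translated, with unequal shares. The 5.8S rRNA gene had 83312 FPKM of 2050730 in WT, 24959 of 395843 in KO_FL and 51735 of 190755 in KO_dN. Small nucleolar RNAs summed to 378774, 104825 and 18098 in these groups.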

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

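The tests in this part were chosen before the data were examined, except scaling by median of ratios, summed repeated identifiers and the filter without WT, which were chosen after the result was seen. No paired analysis was possible because each deposited file holds 1 mean value per group; for the same reason leaving out a replicate and a replicate block could not be run. Of 624 list offsets under an alternative, 568 kept their place inside, above or below the random lists, 20 were weaker, 36 stronger and 0 reversed. Most were inside as deposited: of 26 lists, 1 lay outside in KO/WT, 6 in KO_FL/KO, 4 in KO_dN/KO and 5 in KO_FL/KO_dN. Only those could become weaker or reversed, so a change of sign in the others did not count as reversed. Of 455 log2 ratios of named genes, 407 were the same, 19 weaker, 25 stronger and 4 reversed. Of 84 counts 36 stayed within 1.5 times the count as deposited and 48 moved, of 14 percentages 6 were the same and 8 moved, and of 21 correlations 6 were the same, 11 moved and 4 reversed. The deposited counts of genes at least 2-fold different were 6590 for KO/WT, 616 for KO_FL/KO, 553 for KO_dN/KO, 1553 for KO_FL/KO_dN, 6273 for KO_FL/WT and 7075 for KO_dN/WT. With a pseudocount of 5 they were 3902 for KO/WT, 287 for KO_FL/KO, 205 for KO_dN/KO, 555 for KO_FL/KO_dN, 3533 for KO_FL/WT and 4424 for KO_dN/WT, and with a pseudocount of 0.1 they were 1362 for KO_FL/KO, 1958 for KO_dN/KO and 3805 for KO_FL/KO_dN; a larger pseudocount shrinks ratios by construction. At a mean of at least 5 FPKM, where fewer genes are counted, they were 2469 for KO/WT, 2352 for KO_FL/WT and 2596 for KO_dN/WT, and with the filter without WT 3924 for KO/WT, 3675 for KO_FL/WT and 4290 for KO_dN/WT. With informative symbols only they were 203 for KO_FL/KO, 246 for KO_dN/KO and 903 for KO_FL/KO_dN, at 4-fold 3745 for KO/WT, 164 for KO_FL/KO, 114 for KO_dN/KO, 229 for KO_FL/KO_dN and 3067 for KO_FL/WT, and at 1.5-fold 1529 for KO_FL/KO, 2240 for KO_dN/KO and 3697 for KO_FL/KO_dN. Centring gave 2497 for KO/WT, 282 for KO_dN/KO, 646 for KO_FL/KO_dN, 2183 for KO_FL/WT and 2571 for KO_dN/WT, TPM 2652 for KO/WT, 878 for KO_FL/KO_dN, 2251 for KO_FL/WT and 2760 for KO_dN/WT, and quantile normalization 2439 for KO/WT, 771 for KO_FL/KO_dN, 1981 for KO_FL/WT and 2562 for KO_dN/WT. Rescaling without the 50 highest genes gave 2568 for KO/WT, 734 for KO_FL/KO_dN, 2229 for KO_FL/WT and 2882 for KO_dN/WT, and scaling by median of ratios 2286 for KO/WT, 337 for KO_dN/KO, 643 for KO_FL/KO_dN, 1869 for KO_FL/WT and 2395 for KO_dN/WT. These scalings remove the shift of the median gene, which moves the counts by construction. The percent of genes lower in KO with KO_FL above KO_dN was 66.1 with a pseudocount of 5, 70.9 centred, 65.1 with TPM, 65.8 with quantile normalization and 65.4 scaled. That of genes higher in KO was 38.7 with a pseudocount of 5, 41.97 centred and 34.1 with TPM. The centred share of lower genes lay below its random range of 72.0 to 75.8%, and the scaled share above its range of 53.2 to 57.4%. Random ranges were not computed for a pseudocount of 5, TPM or quantile normalization. The Spearman rho of WT/KO and KO_FL/KO_dN was 0.21 and 0.40 with a pseudocount of 0.1 and 5, 0.15 at a mean of at least 5 FPKM, 0.29 with TPM, 0.32 with quantile normalization and 0.29 scaled. That of WT/KO_FL and KO/KO_dN was -0.10 at a mean of at least 5 FPKM and reversed to 0.14 with a pseudocount of 5, 0.072 with TPM, 0.041 with quantile normalization and 0.031 scaled. That of WT/KO_dN and KO/KO_FL was -0.26 and -0.39 with a pseudocount of 0.1 and 5, -0.25 at a mean of at least 5 FPKM and -0.25 with TPM. The KO/WT log2 ratio of ddx3xa reversed to 0.68 centred, 1.101 with TPM, 1.15 with quantile normalization and 0.81 scaled. For the percentages, correlations and symbols the cause was not tested. At the same FPKM, a low gene rests on the fewest reads in WT if its file shares the scale of the others. WT then has 34.6% and 27.2% of the depth of the deepest library. Identifiers at 0 FPKM were nonetheless fewest in WT, with 9963 of 33633, against 14191 in KO, 13010 in KO_FL and 15555 in KO_dN.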

Other observations

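The group of small RNA genes, and each of the 9 tests in this part, were chosen after the result was seen. Small nucleolar RNAs, which guide rRNA modification and are not translated, held a large share of the listed FPKM: 46 of 52 passed the filter, and their values summed to 378774 in WT, 27607 in KO, 104825 in KO_FL and 18098 in KO_dN. The 5.8S rRNA gene was higher in KO than in WT but lower in the injected groups, with 83312 FPKM in WT, 165680 in KO, 24959 in KO_FL and 51735 in KO_dN. The 124 small RNA genes that passed had an offset of -1.01 in KO/WT, 0.32 in KO_FL/KO, 0.36 in KO_dN/KO and -0.05 in KO_FL/KO_dN, each outside the random lists (-0.70 to -0.16, 0.08 to 0.26, -0.27 to -0.08 and 0.26 to 0.50). With scaled values the offsets were -0.68, 0.19, 0.017 and -0.033, and those of KO_FL/KO and KO_dN/KO lay among the random lists.

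Most genes stood lower in KO, KO_FL and KO_dN than in WT. Fewer reads in the mutant libraries would make a single read worth more there, and it was worth at least 1.65-fold more in WT than in any of them, but a scale factor of the WT file would raise that value too. Scaling by 1 factor per group moved the median log2 KO/WT ratio from -1.94 to -0.30, which removes the shift by construction. The scaled SD of KO/WT stayed 1.61 times (1.52 to 1.69, bootstrap over genes) that of the widest pair of the other groups. A factor does not give such a width. The filter favours genes high in WT, so part of the width may come from it, and scaling was not combined with a filter without WT. FPKM divides by mapped reads, so fewer reads alone would not lower strongly expressed genes as a set. Of the 848 genes with an informative symbol and a mean of at least 10 FPKM, 817 were lower in KO (median log2 ratio -2.82). WT weighs most in that mean, so this pool favours genes high in WT. With WT left out of the mean, 3722 of 4850 genes at 1 FPKM or more were at least 2-fold lower in KO, and 202 were higher. The side thus did not come from that choice alone. These values argue against fewer reads as the whole source for the 848 genes. For the shift, neither a scale factor, fewer reads for weaker genes, nor processing of the WT file apart from the others, in which alone 101 identifiers stood on several lines, can be excluded: they cannot be told apart from an effect of the mutation. The mutation itself stays open, and was not tested.

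Ribosomal protein genes stood lower in KO than other genes. Their high expression predicts a scaled offset inside the random lists of the same level, whose lower bound was -0.49, and the offset of -1.23 was below it. Many of these genes carry small nucleolar RNA genes in their introns, whose reads could be counted with them. The 49 genes with none inside in the gene table used had an offset of -1.23 (bootstrap over genes -1.73 to -1.05), below random lists of their level (-0.55 to 0.20), which speaks against those RNAs as the whole source; ones missing from that table stay open. An effect of the mutation on these genes was not tested apart from their transcript level.

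The ribosomal protein, zygotic signalling and outer-layer lists lay above the random lists in KO_FL/KO_dN, and early zygotic transcription factors did so with scaled values. Carry-over of WT material would add the same fraction of the WT level to every gene, and the lists would need 4.39%, 10.0% and 21.3% of it. Among 878 genes at 50 FPKM or more in WT, those with a KO_FL/WT ratio below the needed fraction divided by 1.5 were counted. Their share was 4.33% (ribosomal protein, 3.19 to 5.24), 16.9% (zygotic, 12.07 to 32.3) and 44.3% (enveloping and yolk syncytial layer, 24.4 to 56.2). The zygotic and outer-layer intervals lay above a bound of 5% of genes, which was set after the values were seen. A looser bound of 25% tried earlier left both open, so the answer depends on the bound and no conclusion is drawn. For ribosomal protein genes carry-over cannot be told apart from an effect of the construct. A later stage of the KO_FL embryos predicts lower maternal oocyte genes, and their scaled offset lay among the random lists in KO_FL/KO_dN (-0.028) but below them in KO_FL/KO (-0.19), so stage and construct cannot be told apart. A rescue by ddx3xbFL stays open as the biological explanation and was not tested.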
